A study of Homo sapiens with 18 samples.

How the data were processed

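Total RNA from the SCLC lines H510, H526 and H1417, kept for 72 h with DMSO or with T-3775440 at 500 nmol/L, was measured on 18 Agilent arrays of 1 colour, 3 per line and treatment per the labels. The labelling text in the labels names a kit for Illumina arrays although the files come from an Agilent scanner. The scanner files hold signal intensities that the submitters' software, Agilent Feature Extraction 11.0.1.1, had background-subtracted and spatially detrended, per the file headers, with no scaling between arrays. The same files hold raw median intensities of each spot and its local background, and flags (unit other, 0 or 1) for spots well above background, saturated or uneven, per the file headers. The deposited value table holds the same intensities, each array multiplied by a constant that puts its 75th percentile at 100, a step found from the values and stated nowhere in the labels. Whether replicates came from separate cultures, and on which days, is not given in the sources used here, and no pooling is stated.

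Each array had 58717 spots. Signals were put on the log2 scale relative to the 75th percentile of their array, which lay between 726 and 965 in signal units. Spots that the scanner software marked as uneven or as outliers were left out, and the others were averaged over the spots of a probe. Of 50599 gene probes, 28174 were matched to a gene through their transcript accession in a table of current RefSeq accessions, and 22425 stayed unnamed and were left out of the gene results. Among 25219 probes for RefSeq messenger RNAs 24546 were named. The probes covered 20503 genes, of which 5767 had several probes and were represented by the brightest. Among called genes with a change of at least 2-fold and several probes, 5 of 94 in H510, 1 of 60 in H526 and 1 of 58 in H1417 had a probe of the opposite sign. Coordinates are not printed, since the array is annotated on an older genome build than the accession table. A gene was tested in a comparison when it was well above background on all 3 arrays of at least 1 of the groups compared.

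Differences were tested with limma 3.58.1 in R 4.3.3, in a single fit of the 18 arrays with 6 groups and 12 residual degrees of freedom, two-sided, with adjustment by Benjamini-Hochberg within each comparison and a threshold of 0.05. The comparisons were T-3775440 minus DMSO in each line, genes changed the same way in all 3 lines, the interaction of line and treatment, and the lines under DMSO. Where a gene was below background on every array of a group, the fold is a lower bound. It sets the mean of the bright group against the mean of the dim group, with each dim array taken at the higher of its lowest signal well above background and the probe's own signal. The 26 gene lists, fixed before the data were examined with all other choices unless stated, were tested with camera at a preset correlation of 0.01 where at least 5 genes were tested, adjusted over all 76 tests of list and line. Of the 25 calls 5 held with an estimated correlation, and the lists overlap, with 6 of the 34 mesenchymal and 3 of the 42 neuroendocrine genes also in another list. The LSD1 complex list has 14 genes and the neuroendocrine list 42.

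The genes named were set by a rule. It takes the genes the series concerns, KDM1A, INSM1 and GFI1B among them, and in each line the 8 risen and the 8 fallen genes with the largest change among those past the threshold whose groups do not overlap. It adds up to 4 members of each list with the smallest adjusted p, the 8 risen and 8 fallen genes with the largest change in all 3 lines, and the 10 genes whose change differed most between the lines. Under DMSO it takes lineage and MYC family genes and the 5 genes that stood highest above both other lines in each line. Some results under the rule are not reported here. Any other gene is named as chosen after its values were seen.

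Slides were read from the file headers, 8, 8 and 2 arrays on 3 slides, each scanned on its own. The alternatives tried were quantile normalization, median centring, no filter and a stricter filter on dim probes, the mean over a gene's probes, the slide as a fixed or a random block, a block by replicate number, each line fitted on its own, the arrays of a single slide, an intensity trend with a robust prior, array weights, the deposited table, other thresholds, other list tests and leaving out each array. A background correction by normexp was planned on mean signals, which the files do not hold, and was run on median signals with an offset of 50, a choice made after the files were seen. Sample numbers do not pair the samples.

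The fit was tested on simulated data, made from each gene's DMSO mean per line, normal noise with the gene's own residual spread, and known changes in chosen genes. At a log2 change of 0.5 it found 67.2% of the changed genes in H510, 80.6% in H526 and 79.1% in H1417, and at 1 it found 95.5%, 89.6% and 86.6%. Unchanged genes made up 2.25%, 0.503% and 4.35% of the calls. The interaction found 82.0% of 618 changed genes, and the list test found the single shifted list and no other. The noise was independent between genes and held no slide effect, so false list calls from correlated genes could not appear. Genes changed singly were drawn from those above background on every array of their line. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.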

Results

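Messenger RNA was measured with 18 Agilent arrays of 1 colour in 3 small cell lung cancer (SCLC) lines, H510, H526 and H1417. Cells were kept for 72 h with 500 nmol/L T-3775440, an inhibitor of the histone demethylase LSD1, or with the solvent DMSO, with 3 arrays for each line and treatment. The comparison of treated with DMSO cells asks in each line which transcripts moved with the inhibitor, and the tests between lines ask where the responses differed. Between 55.9% and 61.2% of the 58717 spots of an array were well above background, no spot was saturated, and the number of arrays limits the precision. After scaling, the 75th percentile of every array lay at 0 on the log2 scale, and replicate arrays correlated with r between 0.9957 and 0.9988 across genes. The leading principal components, with 51.2% and 42.5% of the variance, separated the lines, and the next, with 1.88%, separated treated from DMSO arrays. Changes are log2 differences, T-3775440 minus DMSO, ± the standard error of a limma fit over all arrays (n = 3 per group). A gene below background on every array of a group has only a bound, printed as "at least" a fold with the fit's adjusted p. Nothing states that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

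The arrays lay on 3 slides, and each slide was its own scan. Slide 1 held the DMSO arrays of H510 and H526 and H510 treated replicates 2 and 3. Slide 2 held the treated arrays of H526, the DMSO arrays of H1417 and H1417 treated replicates 1 and 2. The other 2 treated arrays lay on slide 3. Treated and DMSO arrays shared a slide in H510 and H1417 but never in H526. For H526 a fit with the slide as a block rests on the 2 arrays of slide 3, and the results below say where it ended a call or moved a fold by over 1.5 times. The differences of lists between lines were not run with the block.

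The series concerns LSD1 and the SNAG domain factors INSM1 and GFI1B, transcriptional regulators that recruit LSD1. KDM1A, the gene of LSD1, passed the test in no line, with changes of -0.01 ± 0.08 in H510, -0.02 ± 0.08 in H526 and -0.03 ± 0.08 in H1417 (adjusted p = 0.946, 0.901 and 0.814). INSM1 fell by 0.54 ± 0.07 in H510 (adjusted p = 5.05e-05) and by 0.26 ± 0.07 in H1417 (0.0132). It rose by 0.45 ± 0.07 in H526 (0.000215). Its change differed between the lines (adjusted p = 8.24e-06 for the interaction). GFI1B, a repressor best known from blood cells, was far above background in H526 alone, where its change of 0.52 ± 0.26 missed the threshold (adjusted p = 0.134) although the treated and DMSO values did not overlap. That error pools the spread of all groups. The SDs under DMSO and treatment were 0.090 and 0.067 in H526, but 0.29 and 0.70 in H1417, where GFI1B was below background. In H510 its value was -0.17 ± 0.26 (0.660), with 1 of 3 treated arrays above background. With the same pooled error the lines' changes were not shown to differ (0.266).

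Of the 14 tested members of the LSD1 complex list, 1 rose and 2 fell in H510, while 2 fell in H526 and 2 in H1417, with the same counts adjusted over the list alone, and the list passed the test in no line (adjusted p = 0.95, 0.865 and 0.725). HMG20B, a DNA-binding subunit, fell by 0.38 ± 0.07, 0.33 ± 0.07 and 0.48 ± 0.07 in H510, H526 and H1417. The median had another sign than the mean or the test for this list in H510 and H526. With median centring HMG20B in H510 missed the threshold (-0.32, 0.0524, against 5.63e-05 in the setting with the lowest adjusted p).

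With the slide as a block, INSM1 in H526 rose by 0.42 ± 0.11 (adjusted p = 0.0318) and GFI1B in H526 by 1.44 ± 0.33 (0.0160). The slide terms come from the treated arrays of H510 and H1417. GFI1B was above background there on 1 of 3 and 0 of 3 arrays. For GFI1B these terms thus largely measure background, and 1.44 cannot be read as a rise corrected for the slide. GFI1B in H526 also passed when H1417 treated replicate 3 was left out (0.52, adjusted p = 0.0123), when H526 was fitted alone (0.52, 0.00403), with weights per array (0.54, 0.0272) or with another background correction (0.56, 4.23e-06), and its adjusted p over all settings reached 0.259. The fall of INSM1 in H1417 missed the threshold without H1417 treated replicate 2 (-0.19, adjusted p = 0.0606), with median centring (-0.23, 0.253), with H1417 fitted alone (-0.26, 0.0826) and on the arrays of slide 2 alone (-0.33, 0.0503). Its adjusted p over all settings was 0.000561 to 0.253. On slide 1 alone, INSM1 in H510 changed by -0.61.

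**Figure D1:**
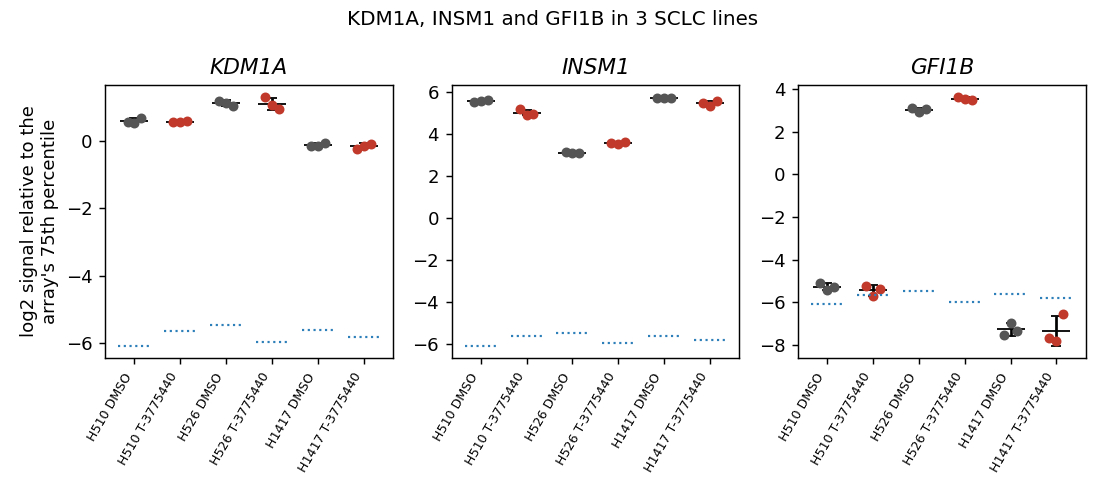
Log2 signal relative to the 75th percentile of the array for KDM1A, INSM1 and GFI1B in each line and treatment. Each point is an array, the long bars are means of 3 arrays with their SD, and the dotted lines mark the mean of the lowest signal well above background, under which GFI1B lay in H1417; INSM1 fell by 0.54 in H510.

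H510 cells lost neuroendocrine transcripts and gained genes of the non-neuroendocrine SCLC state. SCGN, a calcium-binding protein of neuroendocrine cells, fell by 5.37 ± 0.09 (adjusted p = 7.65e-14), and NSG2, a neuronal vesicle protein, by 3.55 ± 0.07 (2.7e-13). The sodium-calcium exchanger SLC8A3 was at least 15.4-fold lower (1.48e-09) and the vesicular monoamine transporter SLC18A1 at least 3.47-fold (5.95e-14). The chemokine CXCL13 was at least 3.70-fold lower (1.23e-10) and the cold-sensing channel TRPM8 at least 3.98-fold (1.91e-07). NPPA, a natriuretic peptide, fell by 3.95 ± 0.14 (8.92e-11; 2 of 3 treated arrays above background) and PDZRN3 by 3.61 ± 0.18 (2.36e-09; 1 of 3). The scavenger receptor SCARA5 was at least 46.2-fold higher (3.79e-10) and LRRN4 at least 28.2-fold (1.93e-10). The phosphate transporter SLC34A2, a marker of alveolar epithelium, rose by 3.95 ± 0.45 (9.6e-06). DSCAM, a neural adhesion molecule, rose by 3.70 ± 0.13 (4.91e-11), and YAP1, the Hippo pathway coactivator, by 3.59 ± 0.17 (1.48e-09; 1 of 3 DMSO arrays above background). The sodium channel subunit SCNN1G, carbonic anhydrase CA12 and KIAA1210 were at least 6.09-fold, 4.06-fold and 4.58-fold higher.

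By list, 35 of the 42 tested neuroendocrine markers fell in H510, 1 rose and 6 did not pass, with the same counts adjusted over the list alone (median -0.64, adjusted p = 7.47e-37). GRP, a neuropeptide, fell by 3.34 ± 0.09, SYT4 and SEZ6 by 3.02 ± 0.07 and 1.80 ± 0.05, and PCSK1, a prohormone convertase, by 1.62 ± 0.05. Of 23 non-neuroendocrine markers 18 rose and none fell, also when adjusted over the list alone (median 1.21, 4.42e-29). Among them were the protease PLAU (3.40 ± 0.07), the intermediate filament VIM (3.01 ± 0.10), the integrin ITGB4 (2.58 ± 0.12) and the membrane protein IFITM2 (2.37 ± 0.11). Of 53 synaptic and neuronal genes, 28 fell and 4 rose (33 and 4 adjusted over the list alone; median -0.39, adjusted p = 6.9e-12). The falls were 2.75 ± 0.06 in SV2B, 1.91 ± 0.08 in RAB3B, 1.36 ± 0.06 in the transcription factor POU4F1 and 0.88 ± 0.05 in CADPS. These 3 calls held with an estimated correlation between the genes (adjusted p = 0.00741, 7.41e-05 and 0.00119).

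A further 6 lists passed in H510 without keeping their call under an estimated correlation. Of 19 genes of the integrated stress response 13 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.41, adjusted p = 1.07e-06, and adjusted p = 0.219 with an estimated correlation). Falls were 1.52 ± 0.06 in CHAC1, 1.52 ± 0.07 in the cystine transporter SLC7A11 and 0.70 ± 0.06 in asparagine synthetase ASNS. Of 41 proliferation genes 22 fell, none rose and 19 did not pass (26 fell adjusted over the list alone; median -0.19, adjusted p = 0.000846, and adjusted p = 0.339 with an estimated correlation). Among them were CDT1 (-0.48 ± 0.04), RRM2 (-0.54 ± 0.05) and CCNE2 (-0.51 ± 0.05). In the epithelial-mesenchymal and TGF-beta list, 13 of 28 genes rose and 3 fell, also adjusted over the list alone (median 0.27, adjusted p = 0.000561, and adjusted p = 0.0704 with an estimated correlation). ZEB1, a repressor of epithelial genes, rose by 2.91 ± 0.18, and the signal transducers SMAD6 and SMAD3 by 1.18 ± 0.09 and 1.00 ± 0.07. Of 30 Wnt pathway genes 13 rose and 5 fell (14 and 6 adjusted over the list alone; median 0.19, adjusted p = 0.00195, and adjusted p = 0.111 with an estimated correlation). The feedback inhibitors RNF43 and KREMEN1 rose by 1.61 ± 0.05 and 1.32 ± 0.06, whereas the ligand WNT11 and the receptor FZD10 fell by 2.53 ± 0.19 and 1.28 ± 0.09. Immune receptor and adhesion genes passed with 8 of 17 higher and 1 lower, also adjusted over the list alone (median 0.12, adjusted p = 0.0297, and adjusted p = 0.14 with an estimated correlation). The adhesion molecule ICAM1 rose by 1.16 ± 0.12 and the chemokines CXCL3 and CXCL2 by 2.10 ± 0.23 and 1.73 ± 0.18. Lung epithelium markers passed with 4 of 11 higher and none lower, also adjusted over the list alone (median 0.14, adjusted p = 0.0449, and adjusted p = 0.235 with an estimated correlation). The surfactant protein SFTPB rose by 2.96 ± 0.11.

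Across the array 4835 of 15493 tested genes changed in H510, 2169 higher and 2666 lower, of which 389 and 372 changed at least 2-fold. The treated and DMSO values of 7774 genes (50.2%) did not overlap, where random splits of the arrays give 10% on average. All genes share these arrays, so a shift of whole arrays can raise the share for many genes together. With the slide as a block, 1882 genes rose and 2511 fell and all 16 genes named for their size were still called (largest adjusted p = 4.41e-05). On slide 1 alone 4398 genes changed and the 9 list calls held (largest adjusted p = 0.0304). Within-slide medians were -0.64 for neuroendocrine, 1.202 for non-neuroendocrine, -0.41 for synaptic, -0.40 for stress and -0.23 for proliferation genes. They were 0.25 for mesenchymal, 0.18 for Wnt, 0.12 for immune and 0.13 for lung epithelium genes, and the block gave the same values to 2 decimals. The call for immune genes ended with the block (adjusted p = 0.0592), with quantile normalization, with no filter on dim probes and without H510 treated replicate 2. Its adjusted p over all settings ran from 6.4e-06 with fry, a list test that does not compare a list with other genes, to 0.14. The call for lung epithelium ended in 14 of 35 settings (2.45e-07 to 0.235 over all settings, fry included). The Wnt call ended with H510 fitted alone. Centring the arrays on their median in place of the 75th percentile moved the share of higher calls in H510 from 44.9% to 56.9%, and quantile normalization to 53.03%.

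H526 cells gained the transcription factors NEUROD1 and ZEB1 and lost muscle actins. UMODL1 was at least 20.3-fold higher by its brightest probe (adjusted p = 2.35e-10), while another UMODL1 probe, above background on 1 DMSO array and no treated one, was at -1.85. The remaining UMODL1 probe, above background on every treated and no DMSO array, had a fitted value of 5.56. ZEB1 was at least 16.9-fold higher (3.66e-11) and the TGF-beta binding protein LTBP1 at least 7.54-fold (7.32e-07). VEGFD, a lymphatic growth factor, rose by 5.84 ± 0.15 (2.27e-12), IGFBP2, which binds insulin-like growth factors, by 5.17 ± 0.12 (1.02e-12), and FOXI1, an ionocyte transcription factor, by 4.71 ± 0.22 (1.41e-09). SEPTIN10, a cytoskeletal GTPase, and TOX3 rose by 4.32 ± 0.05 and 4.29 ± 0.12 (1.46e-15 and 7.6e-12). The actins ACTG2, ACTA1 and ACTA2 fell by 4.37 ± 0.16, 3.66 ± 0.10 and 3.55 ± 0.10 (1.04e-10, 7.6e-12 and 6.53e-12), with 1 of 3 treated arrays above background for ACTA2. LUM, an extracellular matrix proteoglycan, fell by 3.18 ± 0.11 (8.08e-11) and PYGL, the liver glycogen phosphorylase, by 2.84 ± 0.10 (6.54e-11). The glucosidase GBA3, the bile acid receptor NR1H4 and ART3 were at least 20.8-fold, 7.24-fold and 5.25-fold lower.

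Neuroendocrine markers did not pass as a list in H526: of 36 tested genes 8 rose, 14 fell and 14 did not pass (9 and 16 adjusted over the list alone), with a median of -0.10, a mean of 0.01 and adjusted p = 0.782. NEUROD1, a neurogenic transcription factor, rose by 3.69 ± 0.07 (2.77e-13), STMN2 by 2.17 ± 0.07 and the adhesion molecule NCAM1 by 0.90 ± 0.05, while PCSK1 fell by 1.03 ± 0.05. Synaptic and neuronal genes likewise moved both ways, 12 of 45 higher and 13 lower (12 and 14 adjusted over the list alone; median -0.07, mean 0.11, adjusted p = 0.59). ELAVL3, CADPS and MAP2 rose by 2.08 ± 0.07, 1.21 ± 0.05 and 0.91 ± 0.05. Of 24 non-neuroendocrine markers 13 rose and 3 fell (14 and 3 adjusted over the list alone; median 0.35, adjusted p = 0.000301, and adjusted p = 0.0454 with an estimated correlation). VIM rose by 4.08 ± 0.10, YAP1 by 3.13 ± 0.17 and S100A10 by 0.92 ± 0.07. Among 23 mesenchymal and TGF-beta genes 11 rose and 5 fell (12 and 6 adjusted over the list alone; median 0.15, adjusted p = 3.94e-07, and adjusted p = 0.0713 with an estimated correlation). ZEB2, a relative of ZEB1, was at least 2.42-fold higher and N-cadherin, CDH2, rose by 1.19 ± 0.07. Of 23 Wnt pathway genes 13 rose and 5 fell (14 and 5 adjusted over the list alone; median 0.40, or 0.31 with genes below background at their bound; adjusted p = 1.23e-07, and adjusted p = 0.111 with an estimated correlation). SP5, a target of Wnt signalling, rose by 3.22 ± 0.07 and KREMEN1 by 2.75 ± 0.06, the ligand WNT5A was at least 4.30-fold higher, and the receptor FZD5 fell by 0.81 ± 0.05.

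Integrated stress response genes fell in H526 too, 13 of 19 lower and 2 higher, also adjusted over the list alone (median -0.34, adjusted p = 1.07e-06, and adjusted p = 0.232 with an estimated correlation). Falls were 1.22 ± 0.06 in CHAC1, 1.09 ± 0.06 in ATF5, 0.99 ± 0.07 in SLC7A11 and 0.805 ± 0.07 in CEBPB. Of 22 cholesterol synthesis genes 14 fell and none rose (17 fell adjusted over the list alone; median -0.26, adjusted p = 0.00376, and adjusted p = 0.339 with an estimated correlation). MSMO1 and LSS, enzymes of the pathway, were at -0.60 ± 0.08 and -0.36 ± 0.05. Of 18 genes of MHC class I antigen presentation 9 fell and none rose (10 fell adjusted over the list alone; median -0.19, adjusted p = 0.0449, and adjusted p = 0.379 with an estimated correlation). Among them were HLA-G (-0.54 ± 0.07), HLA-E (-0.51 ± 0.07) and HLA-B (-0.41 ± 0.06). The fibroblast list passed with 2 of 11 genes lower and 2 higher, also adjusted over the list alone (median -0.01, mean -0.55, adjusted p = 0.00155, and adjusted p = 0.592 with an estimated correlation). The fallen genes were ACTA2 and LUM, and the risen ones PDGFRA (1.40 ± 0.28) and S100A4 (0.29 ± 0.10). Proliferation genes did not pass, with 9 of 41 higher and 2 lower (8 and 0 adjusted over the list alone; median 0.03, adjusted p = 0.59).

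Across the array 5977 of 15166 tested genes changed in H526, 2761 higher and 3216 lower, with 457 and 158 at least 2-fold. The values of 8392 genes (55.3%) did not overlap, against an average of 10% over random splits, with the same limit as in H510. Median centring moved the share of higher calls from 46.2% to 42.8%, and quantile normalization turned the majority, to 51.0%. No slide held both groups, so no within-slide value exists. The slide block left 1619 calls, 978 higher and 641 lower, of which 451 and 163 reached 2-fold. It kept 415 of the 615 changes of at least 2-fold (67.5%) and 960 of the 5362 smaller ones (17.9%), while the median standard error grew from 0.143 to 0.310 and from 0.0693 to 0.152. All 16 genes named for their size passed with the block (largest adjusted p = 0.0218), but FOXI1 moved to 3.32 ± 0.20, and the fitted values of GBA3 and LTBP1, which are not folds, moved from -4.67 to -3.70 and from 4.31 to 3.64. The list medians became 0.22 for non-neuroendocrine, 0.23 for mesenchymal, 0.42 for Wnt, -0.35 for stress and -0.35 for fibroblast genes (largest adjusted p = 0.000655). The lists of cholesterol synthesis (median -0.16, adjusted p = 0.0916, and 7.09e-05 to 0.339 over all settings) and MHC class I (-0.18, 0.203, and 0.000124 to 0.379) lost their calls with it, as did the 3 HLA genes named, both cholesterol genes, PDGFRA and S100A4. The lowest value of each range came from fry, which does not compare a list with other genes. The MHC class I call ended in 18 of 34 settings, and that of the fibroblast list also under the stricter filter on dim probes.

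H1417 cells gained Notch pathway genes and the SNAG domain factor SCRT2, and lost NKX2-2, a neural and endocrine homeobox factor that was at least 30.2-fold lower (adjusted p = 2.3e-11). The neuropeptide ADCYAP1 was at least 6.94-fold lower (1.57e-08), the lipid raft protein RFTN1 at least 7.53-fold (5.11e-07) and the kainate receptor GRIK1 at least 5.32-fold (4.14e-12). PPP1R17, a phosphatase inhibitor of neurons, fell by 4.58 ± 0.26 (1.1e-08), the non-coding transcript H19 by 3.65 ± 0.33 (1.18e-06), the laminin LAMB3 by 3.37 ± 0.08 (2.43e-12) and LYG2 by 4.03 ± 0.45 (9.85e-06; 2 of 3 treated arrays above background). MYCL, the MYC family member often amplified in SCLC, rose by 4.31 ± 0.13 (2.18e-11), with 1 of 3 DMSO arrays above background and a further probe below background in both groups. LBH, a transcriptional cofactor, rose by 4.21 ± 0.07 (2.65e-13), the sorting receptor SORCS3 by 3.68 ± 0.08 (8.63e-13) and OSBPL5 by 3.62 ± 0.11 (1.45e-11; 2 of 3 DMSO arrays above background). The hormone receptor PTH1R was at least 7.33-fold higher (1.03e-11), GUCY1B2 at least 7.37-fold (1.75e-08), the kinesin KIF25 at least 4.61-fold (3.17e-06) and the muscarinic receptor CHRM1 at least 2.66-fold (8.12e-06).

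Of 26 Notch pathway genes 12 rose and 4 fell in H1417 (12 and 5 adjusted over the list alone; median 0.11, adjusted p = 1.53e-06, and adjusted p = 0.0339 with an estimated correlation). The ligand JAG1 rose by 1.99 ± 0.07, the effectors HEYL and HEY1 by 1.79 ± 0.07 and 1.24 ± 0.08, and the receptor NOTCH3 by 1.16 ± 0.08. Of 8 SNAG domain factors 4 rose and 2 fell (5 and 2 adjusted over the list alone; median 0.91, or 0.64 with the gene below background at its bound; adjusted p = 0.000468, and adjusted p = 0.218 with an estimated correlation). OVOL1 and OVOL2, regulators of epithelial genes, rose by 1.62 ± 0.06 and 0.76 ± 0.05 and SCRT2 by 2.20 ± 0.16 (2 of 3 DMSO arrays above background), while SNAI1, a regulator of mesenchymal transition, fell by 0.78 ± 0.05. Among 41 neuroendocrine markers 21 fell, 3 rose and 17 did not pass (22 and 4 adjusted over the list alone; median -0.21, adjusted p = 0.00155, and adjusted p = 0.305 with an estimated correlation). Calcitonin, CALCA, and GRP fell by 1.30 ± 0.08 and 1.35 ± 0.09 and the lung factor NKX2-1 rose by 1.64 ± 0.08. Of 14 non-neuroendocrine markers 8 rose and 3 fell, also adjusted over the list alone (median 0.47, or 0.32 with genes below background at their bound; adjusted p = 0.00273, and adjusted p = 0.0928 with an estimated correlation). VIM rose by 2.95 ± 0.10 and the YAP target CCN1 by 0.73 ± 0.06, with ITGB4 at least 1.53-fold higher, and AHNAK, a scaffold protein, at -1.70 ± 0.10. The mesenchymal and TGF-beta list had 10 of 23 genes higher and 2 lower (11 and 3 adjusted over the list alone; median 0.16, adjusted p = 0.000199, and adjusted p = 0.0713 with an estimated correlation). By adjusted p it was led by VIM, SMAD3 (1.26 ± 0.07) and SMAD6 (1.55 ± 0.09), and ZEB1 rose by 2.06 ± 0.18.

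Proliferation genes fell in H1417, 26 of 41 lower and 1 higher, also adjusted over the list alone (median -0.22, adjusted p = 0.000253, and adjusted p = 0.305 with an estimated correlation). Among them were AURKA (-0.43 ± 0.05), RRM2 (-0.40 ± 0.05), BUB1 (-0.38 ± 0.05) and CENPE (-0.35 ± 0.05). Of 49 synaptic and neuronal genes 20 fell and 4 rose (21 and 5 adjusted over the list alone; median -0.11, adjusted p = 0.0134, and adjusted p = 0.146 with an estimated correlation). SV2B and RAB3B were at -0.88 ± 0.06 and -0.88 ± 0.08. Of 23 Wnt pathway genes 9 rose and 3 fell, also adjusted over the list alone (median 0.09, adjusted p = 0.00066, and adjusted p = 0.0995 with an estimated correlation). The receptors FZD7 and FZD4 rose by 1.21 ± 0.08 and 0.86 ± 0.05 and SP5 by 1.01 ± 0.07. The erythroid and megakaryocyte list passed with 4 of 18 genes lower and 2 higher, also adjusted over the list alone (median -0.09, adjusted p = 0.00756, and adjusted p = 0.539 with an estimated correlation). VWF, the von Willebrand factor, fell by 2.78 ± 0.06, the transcription cofactors LMO2 and ZFPM1 by 0.90 ± 0.06 and 0.53 ± 0.06, while the globin HBA2 rose by 0.80 ± 0.10. Integrated stress response genes did not pass, with 3 of 19 higher and 1 lower, also adjusted over the list alone (median -0.04, adjusted p = 0.992).

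Across the array 4230 of 15262 tested genes changed in H1417, 1893 higher and 2337 lower, of which 311 and 206 at least 2-fold. The values of 6425 genes (42.1%) did not overlap, against an average of 10% over random splits, with the same limit as in H510. With the slide as a block 1730 genes rose and 2306 fell, and all 16 genes named for their size passed (largest adjusted p = 0.000100). The arrays of slide 2 alone, with 2 treated arrays, gave 2167 calls, 1094 higher and 1073 lower. All 9 list calls held with the block and within slide 2 (largest adjusted p = 0.00805 and 0.0231). The erythroid call ended with the mean over a gene's probes and with H1417 fitted alone, and the non-neuroendocrine call under the stricter filter on dim probes. Medians within the slide were 0.13 for Notch, 0.92 for SNAG, -0.19 for neuroendocrine, 0.50 for non-neuroendocrine and 0.15 for mesenchymal genes. They were -0.23 for proliferation, -0.15 for synaptic, 0.11 for Wnt and -0.08 for erythroid genes. The medians with the block were the same for the reason given for H510, which is no second check. Median centring moved the share of higher calls in H1417 from 44.8% to 58.5%, and quantile normalization to 52.9%.

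**Figure D2:**
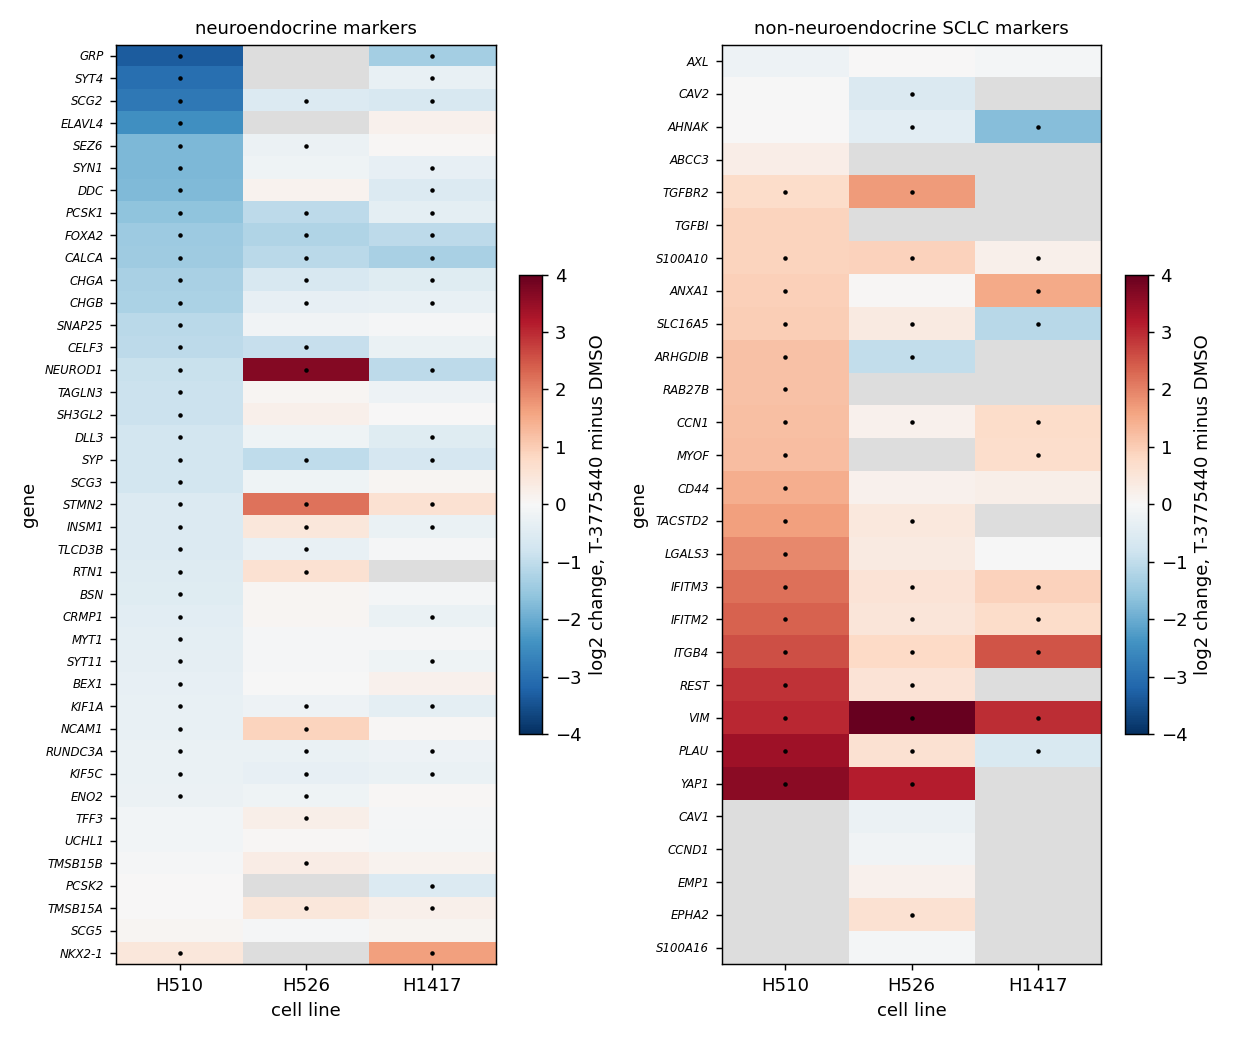
Log2 change, T-3775440 minus DMSO, of the tested neuroendocrine and non-neuroendocrine markers reported here (vertical axis) in each line (horizontal axis), as fitted, with dots on genes that passed the test and grey for genes not tested. Of the whole neuroendocrine list 35 fell in H510, 14 in H526 and 21 in H1417.

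A core of genes responded in the same direction in every line. VIM rose by 3.01 ± 0.10, 4.08 ± 0.10 and 2.95 ± 0.10 in H510, H526 and H1417, and ZEB1 by 2.91 ± 0.18 in H510 and 2.06 ± 0.18 in H1417, beside its bound of 16.9-fold in H526. The chaperone ERP27 rose by 2.61 ± 0.14, 1.75 ± 0.14 and 2.41 ± 0.14. SLC38A8, an amino acid transporter, rose by 2.34 ± 0.10 in H510 and 2.83 ± 0.10 in H1417 and was at least 2.55-fold higher in H526. The phosphatase PTPN14 rose by 1.58 ± 0.15, 1.998 ± 0.15 and 2.11 ± 0.15 (1 of 3 DMSO arrays above background in H1417). UMODL1 rose by 2.55 ± 0.24 in H510 and was at least 2.61-fold higher in H1417. The homeobox gene IRX3 rose by 1.96 ± 0.19 in H510 and 1.46 ± 0.19 in H1417 and was at least 1.97-fold higher in H526. Falling genes included CALCA (-1.43, -1.07 and -1.30; another of its 3 probes was at 0.58 in H526), the foregut factor FOXA2 (-1.46, -1.195 and -1.04), the phosphodiesterase PDE2A (-1.43, -0.76 and -1.996) and the small GTPase RASD1 (-1.0007, -1.30 and -0.73). The nucleotidase ENTPD8 (-1.22, -1.70 and -2.33; 1 of 3 treated arrays above background in H526) and SLC18A1 (a bound of 3.47-fold in H510, then -0.86 and -2.47) fell too. The channel gene ANO4 was at least 3.04-fold and 2.63-fold lower in H510 and H526 and fell by 1.104 in H1417.

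In all, 723 genes changed the same way in every line, 394 higher and 329 lower, out of 13859 tested in each. Independent lists would share 41.4 and 81.2. At 2-fold or more the shared genes were 22 higher and 4 lower, where independence gives 0.0727 and 0.01003. With the slide as a block 271 were shared, and median centring gave 297. EML2 also fell in every line (-0.83, -1.23 and -0.995). The call of EML2 in H510 ended with the block (-0.55, adjusted p = 0.0553) and without DMSO replicate 2 (-0.78, 0.0806), DMSO replicate 3 (-0.78, 0.0773) or treated replicate 1 (-0.55, 0.129). That of EML2 in H526 ended with the block (-1.19, 0.0944), and that of EML2 in H1417 without treated replicate 3 (-0.73, 0.0555) and on slide 2 alone (-0.73, 0.0930). Fitted alone, H510 and H1417 also lost it (0.0621 and 0.0624), and the lowest adjusted p over all settings were 0.0042 for H510, 9.82e-05 for H526 and 0.00156 for H1417. H510 and H526 shared 734 risen and 694 fallen genes (359 and 531 if independent). H510 and H1417 shared 861 and 977 (246 and 391), and H526 and H1417 shared 739 and 778 (316 and 471). Calls in opposite directions numbered 897, 375 and 682 in these pairs, for which no value under independence was computed. In the fit the lines share an estimate of the spread per gene, so calls can coincide in either direction. Independence is therefore only a rough reference for the shared counts. Across genes, which are not independent replicates, the changes correlated with r = 0.15, 0.41 and 0.20 (rho = 0.10, 0.39 and 0.21).

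**Figure D3:**
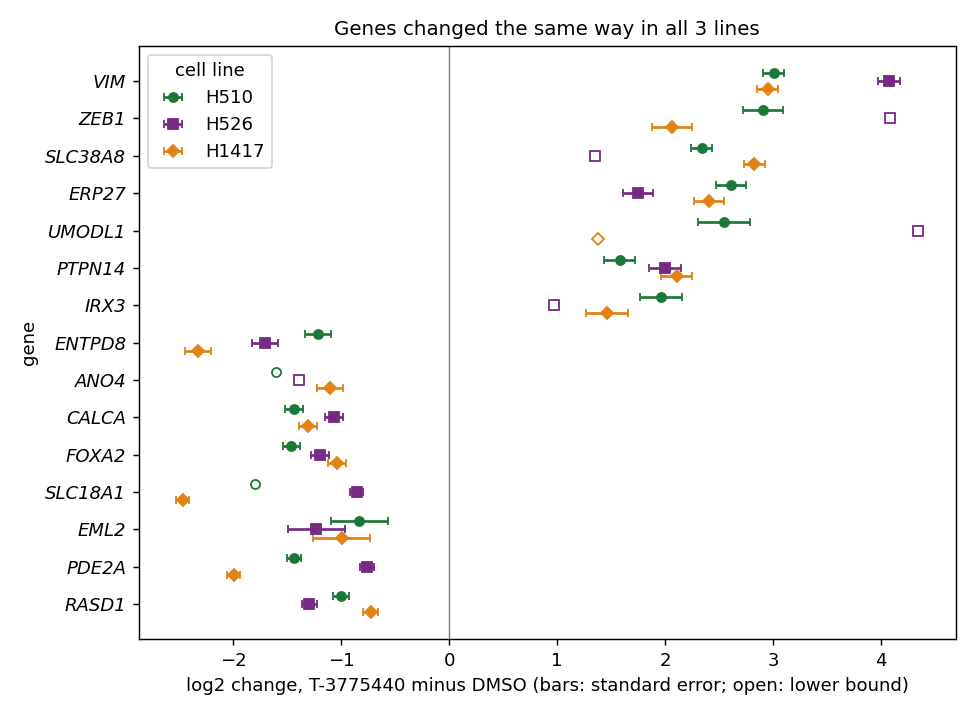
Log2 change, T-3775440 minus DMSO, of 15 genes that changed the same way in every line, with a symbol per line and bars for the standard error (3 arrays per group). Open symbols are lower bounds for genes below background in one treatment; VIM rose by 4.08 in H526.

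The lines differed in much of their response. FOXI1 rose by 4.71 in H526 but fell by 2.81 ± 0.22 in H510, where 1 of 3 treated arrays was above background (adjusted p = 1.23e-09 for the interaction). VEGFD and IGFBP2 rose by 5.84 and 5.17 in H526, while their values were -0.48 ± 0.15 and -0.27 ± 0.12 in H510 and -0.50 and -0.79 in H1417 (3.3e-11 and 1.16e-11). The small fall of VEGFD in H510 missed the threshold with the slide as a block (-0.33, adjusted p = 0.133, and 0.0105 to 0.142 over all settings). LBH rose in H510 and H1417 by 3.22 ± 0.07 and 4.21 ± 0.07 and fell in H526 by 1.04 ± 0.07 (8.19e-13). The cadherin CDH6 rose by 2.43 in H1417 and was at least 2.01-fold lower in H510 (4.14e-11), and SLC8A3 rose by 1.79 in H1417 against its bound of 15.4-fold lower in H510 (3.1e-09). SCARA5 and NKX2-2 were not well above background in the other lines, LRRN4 was at least 2.38-fold higher in H1417 beside 28.2-fold in H510, and PPP1R17 fell by 2.42 ± 0.26 in H510 with 2 of 3 treated arrays above background.

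By the test of the difference itself, 6626 of 16684 genes changed differently between the lines, and 4828 did with the slide as a block. H526 and H510 differed in 5582 genes (1289 by at least 2-fold), H1417 and H510 in 3031 (820), and H1417 and H526 in 4530 (1035). The lists moved apart too. The neuroendocrine list moved further down in H510 than in H526 or H1417 (adjusted p = 1.48e-20 and 2.65e-19, and adjusted p = 0.0194 and 0.0138 with an estimated correlation). So did the synaptic list (3.88e-09 and 5.26e-05, and adjusted p = 0.00413 and 0.00507 with an estimated correlation). Non-neuroendocrine markers moved further up in H510 than in H526 or H1417 (5.12e-06 and 4.35e-15, and adjusted p = 0.00507 and 0.00109 with an estimated correlation). Notch genes moved further up in H1417 than in H510 (0.000675, and adjusted p = 0.0194 with an estimated correlation) or H526 (0.0140, and adjusted p = 0.21 with an estimated correlation). The stress response list differed between H1417 and H510 (3.82e-06, and adjusted p = 0.263 with an estimated correlation) and H1417 and H526 (8.82e-05, and adjusted p = 0.316 with an estimated correlation). The proliferation list differed between H526 and H510 (0.00119, and adjusted p = 0.423 with an estimated correlation) and H1417 and H526 (0.000434, and adjusted p = 0.369 with an estimated correlation). H1417 moved further down than H526 in the synaptic list (median difference -0.19, adjusted p = 0.0140) and than H510 in the immune list (-0.38, 0.0361). It also differed from H510 in the erythroid list (0.000178), where the median was -0.009 beside a mean of -0.45, so the list as a whole did not move. With an estimated correlation adjusted p was 0.21 for all 3. The fibroblast list differed between H526 and H510 (median -0.68, adjusted p = 0.00557, and adjusted p = 0.339 with an estimated correlation). It also differed between H1417 and H526 (0.00913, and adjusted p = 0.408 with an estimated correlation). There the median was 0.052 beside a mean of 0.55, with ACTA2 and LUM at 3.44 and 2.98. The endothelial list differed between H1417 and H510 (5.12e-06, and adjusted p = 0.805 with an estimated correlation), with a median of 0.018 and a mean of -0.55 over 6 genes, so the list as a whole did not move. It also differed between H1417 and H526 (0.000235, and adjusted p = 0.316 with an estimated correlation), with a median of -0.44 and a mean of -0.72 over 5 genes.

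**Figure D4:**
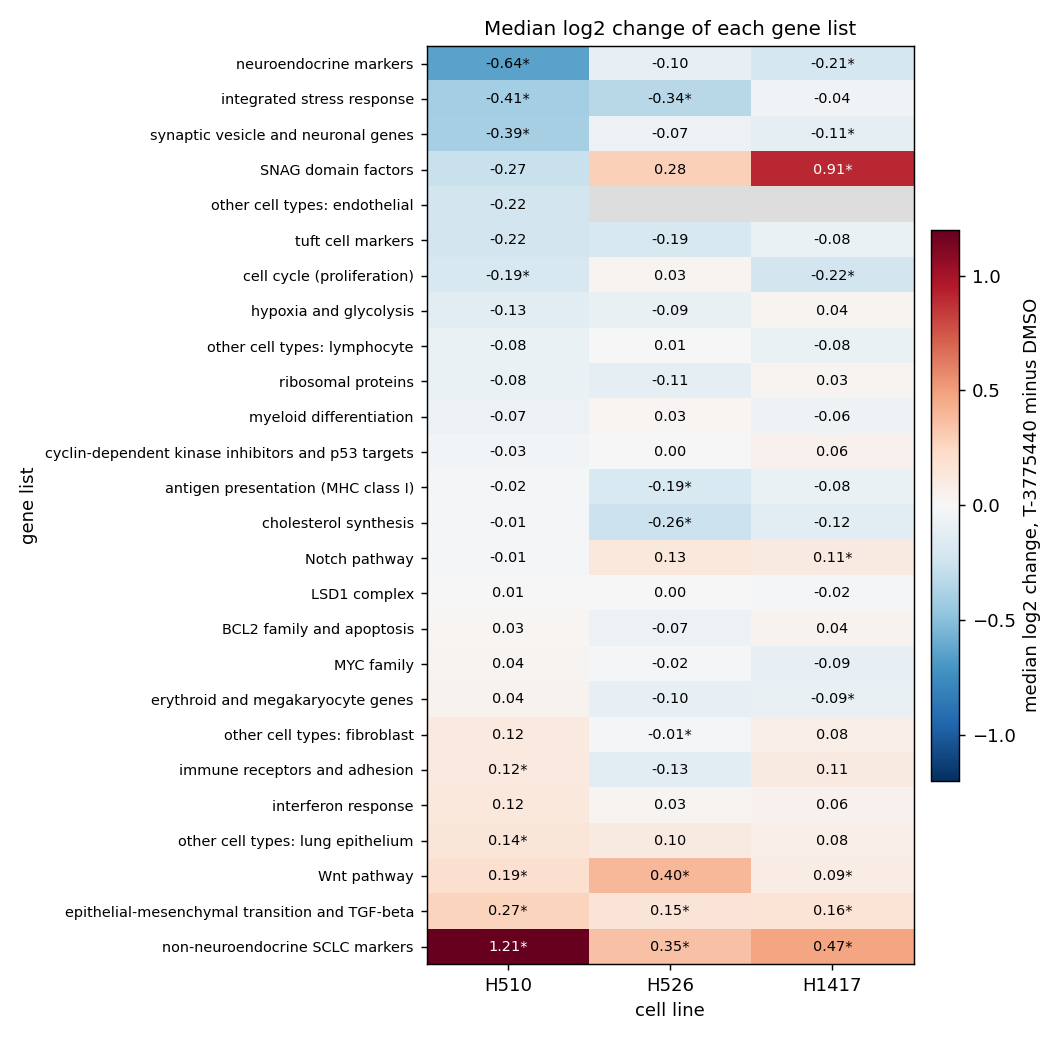
Median log2 change, T-3775440 minus DMSO, of the tested members of each of 26 gene lists (vertical axis) in each line (horizontal axis), printed in the cells, with a star where adjusted p was under 0.05 and grey where fewer than 5 genes were tested. Of 76 tests 25 passed, from -0.64 for neuroendocrine markers to 1.21 for non-neuroendocrine markers in H510.

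Under DMSO the lines differed in their lineage factors, on a log2 scale relative to the 75th percentile of the array (± SD, n = 3). POU2F3, the master factor of tuft cells, stood at 4.34 ± 0.07 in H526, at least 1377-fold and 997-fold above H510 and H1417, both below background (adjusted p = 2.85e-14 over the lines). NEUROD1 was at -0.68 ± 0.06 in H510, -4.92 ± 0.03 in H526 and -1.37 ± 0.08 in H1417. YAP1 was near background, at -4.57 ± 0.15 in H526, above background on 1 of 3 arrays in H510 and on none in H1417. INSM1 was lower in H526 (3.10 ± 0.04) than in H510 (5.54 ± 0.05) and H1417 (5.71 ± 0.02). GFI1B was at 3.04 ± 0.09 in H526, -5.28 ± 0.16 in H510 and below background in H1417. MYCL was at 7.84 ± 0.08 in H510 and 0.60 ± 0.06 in H526, and above background on 1 of 3 arrays in H1417. MYCN was at 5.70 ± 0.03 in H526, 833-fold above H510 and at least 2564-fold above H1417, where it was below background. MYC was at -0.44 ± 0.02 in H510, -1.63 ± 0.06 in H526 and below background in H1417, and KDM1A was at 0.60 ± 0.09, 1.13 ± 0.08 and -0.11 ± 0.05. The genes that stood highest above both other lines included HAPLN1 and the moesin gene MSN in H510, IRAG2, IRX1 and IRX2 in H526, and MS4A8, the kallikrein KLK1 and doublecortin, DCX, in H1417. IRAG2 was at least 7236-fold higher in H526 than in H1417, HAPLN1 at least 1268-fold higher in H510 than in H526, and DCX 636.7-fold higher in H1417 than in H510.

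Of 16417 genes, 15548 differed between the lines under DMSO, 9705 of them at least 2-fold, and 14768 did with the slide as a block. H510 and H526, whose DMSO arrays all lay on slide 1, differed in 13445 of 16024 genes. The difference of INSM1 between H1417 and H510 (0.17 ± 0.07, adjusted p = 0.0456) turned its sign with median centring (-0.17, adjusted p = 0.212).

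The other lists passed in no further line. In H510 the Notch pathway had 7 of 27 genes higher and 8 lower (also adjusted over the list alone; adjusted p = 0.692), with NOTCH3 up by 0.95 ± 0.08 and the inhibitory ligand DLL3 down by 0.74. In H526 it had 8 of 25 higher and 5 lower (0.414). SNAG domain factors had 2 of 9 higher and 3 lower in H510 (0.147; OVOL1 1.52 ± 0.06, OVOL2 1.27 ± 0.05) and 4 of 10 higher and 2 lower in H526 (0.0528; OVOL2 1.19 ± 0.05). In H526 the list passed upward in 12 of 34 settings (9.39e-05 to 0.592 over all settings, fry included). Immune genes had 4 of 13 higher and 5 lower in H526 and 1 of 14 higher and 3 lower in H1417 (both 0.992). Interferon response genes had 8 of 22 higher and 1 lower in H510, 7 and 4 in H526 and 5 and 3 in H1417 (0.0758, 0.336 and 0.433). IFIT1, an antiviral effector, rose by 1.01 ± 0.08 in H510 and 0.56 ± 0.08 in H1417 and was at least 2.91-fold higher in H526. The BCL2 and apoptosis list had 3 higher and 4 lower of 28, 7 and 8 of 27, and 7 and 5 of 25 (0.562, 0.633 and 0.414). The death receptor TNFRSF10B rose by 3.33 ± 0.13 in H510 and 0.91 ± 0.13 in H1417, and the sensitizer BMF by 0.83 ± 0.05 and 0.88 ± 0.05. Kinase inhibitors and p53 targets had 4 higher and 5 lower of 23, 6 and 4 of 22, and 6 and 5 of 20 (0.59, 0.59 and 0.992), with PLK2 up by 2.09 ± 0.07 in H510. The MYC family had 2 and 2 of 11, 1 and 3 of 11, and 2 and 2 of 9 (0.719, 0.782 and 0.109), with MYC up by 0.94 ± 0.19 in H510. Tuft cell markers had 4 higher and 6 lower of 17, 3 and 6 of 24, and 4 and 4 of 14 (0.782, 0.719 and 0.433), and POU2AF3, the partner of POU2F3, rose by 0.55 ± 0.05 in H510 and 0.97 ± 0.05 in H526 and was at least 1.82-fold higher in H1417.

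Hypoxia and glycolysis genes had 3 higher and 7 lower of 25 in H510, 4 and 5 of 24 in H526, and 4 and 3 of 23 in H1417 (adjusted p = 0.436, 0.782 and 0.59). Ribosomal protein genes had 10 of 37 lower in H526 and 1 of 37 higher in H1417 (0.509 in H510, 0.12 and 0.65). MHC class I genes had 2 of 17 higher and 5 lower in H510 and 3 of 18 higher and 6 lower in H1417 (0.992 and 0.226), and cholesterol genes 4 of 22 higher and 4 lower in H510 and 1 higher and 6 lower in H1417 (0.992 and 0.347). Myeloid genes had 2 of 14 higher in H510, 1 of 12 higher and 1 lower in H526, and 1 of 13 higher in H1417 (0.782, 0.782 and 0.923). Erythroid and megakaryocyte genes had 3 of 19 higher in H510 and 1 of 18 higher and 7 lower in H526 (0.226 and 0.214). VWF rose by 1.42 ± 0.06 in H510. Markers of other cell types passed nowhere else: fibroblast 2 of 7 higher and 1 lower in H510 and 1 of 5 higher in H1417 (both 0.782), and lung epithelium 3 of 10 higher and 1 lower in H526 and 1 of 9 higher in H1417 (0.782 and 0.587). Lymphocyte markers moved with none of 7 in H510, 2 of 9 higher and 2 lower in H526 and 1 of 7 lower in H1417 (0.865, 0.923 and 0.147). Endothelial markers, tested in H510 alone, had 1 of 6 higher and 1 lower (0.436). Adjusted over the list alone, the counts of these lists were the same except for Notch in H526 (9 higher and 7 lower), hypoxia in H510 (3 and 8) and H1417 (4 and 4), tuft cell markers in H510 (4 and 7) and H526 (3 and 7), the MYC family (3 and 2 in H510, 2 and 3 in H526, 2 and 3 in H1417) and ribosomal proteins in H1417, where none passed. In 15 of the 76 list tests, none of them called, the median, the mean and the test did not all have the same sign. Beside SNAG factors in H526, lists that passed in some other setting were the interferon response in H510 and the MYC family in H1417, each in 4 of 35 settings with fry among them (lowest adjusted p = 4.23e-06 and 2.45e-07, both with fry). SNAG factors in H510 did so in 3 of 35 (0.00424) and ribosomal proteins in H526 in 2 of 34 (0.0315). Any other did so with fry alone, which does not compare a list with other genes.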

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

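The counts and ranges in the next paragraph stood out because the response was tested to differ between lines. The tests of the slide on the H526 gene counts, of signal strength in H526, of fibroblasts and of cells of another line were chosen after the results were seen; the test of the slide on the neuroendocrine list and the counts of splits were set before.

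The change under T-3775440 differed between H526 and H510 in 5582 genes, between H1417 and H510 in 3031 and between H1417 and H526 in 4530. Among single genes, the range of the log2 change over the lines was 7.51 for FOXI1, between a fall in H510 and a rise in H526. It was 6.45 for PPP1R17, whose fitted value in H526 rests on 2 of 3 treated arrays above background, and 6.35 for SCARA5, which was below background in H526 and H1417. VEGFD had a range of 6.33 and IGFBP2 of 5.97, both with their rise in H526. SLC8A3 had a range of 6.09, low in H510 under the compound and higher in H1417. The range was 5.80 for NKX2-2, which was below background in H510 and H526, and 5.80 for LRRN4, below background in H526. It was 5.33 for CDH6, low in H510 and higher in H1417, and 5.25 for LBH, higher in H510 and H1417 and lower in H526. Ranges that include a group below background are fitted values and not folds.

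Treated and DMSO arrays of H526 never shared a slide, so a slide difference could add to its 5977 changes. With the slide as a block the median ratio of the log2 change to that without it was 1.00 for changes of at least 2-fold and 0.933 for smaller ones. For the larger changes the ratio was not limited to genes above background in H510 and H1417. Where a gene was below background there, as NR1H4 was in both lines, the slide terms measured background and not its signal. A ratio near 1 can arise in such genes with or without a slide difference, so it does not decide for the larger changes. For the smaller ones the quartiles were 0.599 and 1.25, and 960 of 5362 stayed called, so the ratio cannot decide. The slide terms come from arrays of H510 and H1417, so a difference of H526 alone that followed its slides would not show. The calls dropped to 1619 while the median standard error grew from 0.143 to 0.310 for the larger and from 0.0693 to 0.152 for the smaller changes. The block rests on 2 arrays, and 9 of the larger and 265 of the smaller changes took the other sign with it, so a slide effect on single genes, small ones above all, stays open. A response to the compound is the explanation that the design names beside the slide, as a hypothesis.

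Neuroendocrine markers fell as a list in H510 and not in H526, and a signal too low in H526 to show a fall is a candidate explanation. Among 34 members bright in H526, 31 changed more in the upward direction there than in H510, which argues against it for these genes. Their median difference was 0.447 (95% interval over genes 0.303 to 0.921). A slide difference that hides a fall in H526 would, with the slide as a block, bring the list's median near that of H510. In H510 it was -0.64 over 42 genes and -0.54 over the 34 members bright in H526. With the block the median in H526 was -0.18 over 36 genes (interval over genes -0.290 to 0.107). These intervals treat genes as independent, although the list's estimated correlation in H526 was 0.115 and all genes share the same arrays. The latter also leaves out the error that genes share through the slide terms, so a slide difference hiding part of a fall stays open. That the lines respond differently remains as a hypothesis. What sets H526 apart cannot be tested with a single line of its kind.

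The non-neuroendocrine and mesenchymal lists passed upward in every line, and fibroblasts in the treated cultures could bring such transcripts; with an estimated correlation adjusted p = 7.41e-05, 0.0454 and 0.0928 for the former in H510, H526 and H1417 and 0.0704, 0.0713 and 0.0713 for the latter. Of COL1A1, COL1A2, COL3A1 and DCN, abundant in fibroblasts, 0 rose among the 5 of 12 pairs of gene and line that were tested, none of them in H1417, and COL1A2 fell in H510 (-1.44, adjusted p = 8.67e-07), where COL1A1 stood at 0.73 (0.101). COL3A1 was above background on no treated array of any line, nor were COL1A2 and DCN in H1417, while other members of the fibroblast list rose: S100A4 in every line (1.13, 0.29 and 0.34 in H510, H526 and H1417), FBLN1 in H510 (0.18) and PDGFRA in H526 (1.40). In H526, S100A4 and PDGFRA lost their calls with the slide as a block. Cells of another line would raise that line's own genes, whose median log2 change lay at most 0.121 above that of genes below background in every line, over the 6 pairs of lines. These values argue against fibroblasts or cells of the other lines as the source of the whole rise, and a small share of them, cells from elsewhere, a change of state of the lines' own cells, or a subset of them that grew were not tested.

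Other splits of the samples were counted for each number of genes. Within a line the 6 arrays make 10 splits, too few for a share under 0.05: the real split gave 4835 genes in H510, 5977 in H526 and 4230 in H1417, and the highest other 0, 1 and 2, so that 1 of 10 gave as many in each. Over 100 splits drawn, 1, the real one, gave as many as 723 genes changed the same way in all lines (highest other 0). The same held for 6626 genes with an interaction (5195), 25 list calls (21) and 15548 genes between lines under DMSO (8310). A random assignment of labels to these arrays is thus an unlikely source of the counts over 100 splits. A split that mixes treatments or lines puts their difference into the spread, which lowers its count whatever caused that difference. In H526 the real split is also the split by slide, so the counts cannot tell the compound from the slide there. Mixing treated and DMSO arrays within a line also removes the response itself, so the splits do not test whether the lines respond alike. Replicates that may be technical limit every count. The splits with 5195 genes and 21 list calls kept a line as labelled and turned another.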

How the results depend on the processing

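The normexp setting was chosen after the data were seen, and the cause of each move below was not tested unless named. Signal over background limits the folds of dim genes, and no count moved by more than 1.5 times without a single array. Under median centring 2914 genes changed in H510 (1257 lower), 3816 in H526 (1634 higher) and 2329 in H1417 (966 lower), with 297 in all lines and 4263 with an interaction. With the slide as a fixed block the counts were 1619 in H526 (978 higher, 641 lower) and 271 in all lines, where standard errors grew and some estimates moved, and KRT7 in H526 turned to 0.033 (adjusted p = 0.912) and VWF in H526 to 0.068 (0.797). A random block gave 2098 lower in H526, and with no filter, which tests more genes, 3305 were higher in H510. INSM1 under DMSO, H1417 minus H510, turned to -0.17 (0.212) with median centring. Lines fitted on their own gave 1528 lower in H1417 and 436 in all lines, and the arrays of slide 2, fewer samples, gave 2167 in H1417 (1094 higher, 1073 lower). At the stricter threshold of 0.01, 1733 were lower in H510, 2103 lower in H526 and 2793 changed in H1417 (1439 lower), with 410 in all lines. At 2-fold or more 761 changed in H510 (389 higher, 372 lower), 615 in H526 (457, 158), 517 in H1417 (311, 206), 26 in all lines, 1936 with an interaction and 9705 under DMSO. Of the list calls 5 held with an estimated correlation, and fry, which does not compare a list with other genes, gave 49.

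Quantile normalization, the stricter filter, the mean over probes, the intensity trend, array weights and normexp (4533, 6208 and 3890 genes) left every count of changed genes within 1.5 times. The deposited table moved nothing, since it is the same signal times a constant. No called list turned its direction in any setting run. Leaving out an array gave 3969 to 5011 in H510 (1798 to 2224 higher, 2170 to 2795 lower), 4797 to 6235 in H526 (2304 to 2898, 2456 to 3337) and 3451 to 4476 in H1417 (1598 to 1989, 1853 to 2487). It gave 612 to 726 in all lines, 5996 to 6671 with an interaction, 15400 to 15597 under DMSO and 22 to 27 list calls. A block by replicate number, although no pairing of the samples is stated and the numbers do not pair them, gave 4386, 5491 and 3683 genes, 624 in all lines, 5875 with an interaction, 14836 under DMSO and 26 list calls. Among the named genes in H526, 39 of 131 lost their call with the fixed block, 2 turned and 1 gained a call, against 9 of 140 lost in H510 and 4 of 136 in H1417. The 10 genes that differed most between lines kept their calls in every setting run on them, of which 3 were tested under the stricter filter.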

Other observations

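REST, the repressor of neuronal genes and a member of the non-neuroendocrine list, lies outside the naming rule and was chosen after its values were seen. It rose in H510 by 2.90 ± 0.19 (adjusted p = 4.15e-08), where neuroendocrine and synaptic lists fell, and in H526 by 0.55 (0.0352), and was not tested in H1417; no link to those lists was tested. Probes without a gene name also moved: 278 of 7221 tested were higher and 516 lower in H510, 477 of 7201 higher and 293 lower in H526, and 274 of 7768 higher and 215 lower in H1417.

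An inhibitor of a demethylase that acts with repressors could release silent genes, so that risen genes come from below background more often than fallen genes go there. This hypothesis and its bound were written before the shares were counted, and the single floor below was chosen after. In H510 the difference of the shares was -9.52 percentage points, with 32 of 389 genes risen at least 2-fold below background under DMSO and 66 of 372 fallen ones below it under the compound (Fisher's exact test, adjusted p = 0.000135). Genes above background per array fell there from 15724 ± 135 to 15303 ± 75.002 (SD, n = 3), which moves the difference down, but with a single floor for all arrays of the line it was -4.33 points, still under the bound of 10. In H1417 it was 3.59 points (64 of 311 and 35 of 206, exact p = 0.361), and 0.0265 with a single floor. In H526 it was 22.7 points (147 of 457 and 15 of 158, exact adjusted p = 1.36e-08), and 15.1 with a single floor. The exact tests treat genes as independent although all genes of a line share the same arrays. None was run on the counts with a single floor. In H526 the genes above background per array also rose, from 14878 ± 68.4 to 15425 ± 108. Each treated array there lay on another slide than the DMSO arrays. The lowest log2 signal well above background was -5.84 to -6.09 on treated and -5.46 to -5.51 on DMSO arrays of H526. Slide 2 was not lower as a whole, with -5.44 to -5.80 in H1417 there against -5.54 to -6.17 in H510 on slide 1. A release of silent genes and a lower background of the treated H526 arrays cannot be told apart.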
